A study of Mus musculus with 68 samples.

How the data were processed

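Whole-transcriptome libraries of 23 intestinal specimens were compared, with 15 specimens in run 1 and 19 in run 2. Per the labels' protocols, tissue was kept in RNAlater, RNA was purified on RNeasy columns, and libraries were made from polyadenylated RNA. The submitters' processing notes name FastQC, TopHat2 2.0.13, Cuffnorm and the mm10 build, with no version for Cuffnorm. The authors deposited FPKM values, which divide fragments by transcript length and library size, in 1 table of 23356 rows and 68 columns, with 4 columns for each specimen in both runs and 2 for the others. The table carries no counts. Relative depth was taken from the commonest ratio between columns of values up to 0.2, and the sums of the columns ran from 476233 to 801309, with 26.5% to 30.8% of values at 0. FPKM steps depend on transcript length, so depth limits mainly genes of low FPKM, and no counting interval was computed. In the table, 27 gene names had been turned into dates, of which 21 were tested under those names, and 2 names were repeated.

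The design text counts 23 mice and 3 normals per group, while the labels hold 10 animal numbers and 2 per group. Colon is labelled whole tissue and duodenum epithelium, while the design text gives colon epithelial cells and whole duodenum without villi. The protocol describes the floxed allele with Villin-Cre for Apc wildtype mice, and the alleles of the ApcMin mice are not given in the sources used here. Gene positions come from the GRCm38 (mm10) annotation. Without strand information, overlapping genes and near-identical copies were treated as uncertain.

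Columns were averaged per specimen. Genes at 1 FPKM or more in at least 2 specimens were tested, 14098 in all, as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), with Benjamini-Hochberg adjustment at 0.05. Fold changes are on that log2(FPKM + 1) scale, which understates changes of low genes. All groups shared one estimate of spread, except that the duodenal tumours of both Apc genotypes were compared in run 1 columns, and the ApcMin colon tumours against colon in run 2 columns. Heterozygous and wildtype colon tumours, read in different runs, were compared with a run term and the specimen as a random block (correlation 0.878). With 2 specimens per group an exact permutation test cannot go below p = 0.333. The test, the samples of each fit, the gene lists and the naming rule were fixed before the data were examined. Counting the wildtype duodenum as 1 sample departed from that plan.

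Of 39 lists, those with at least 4 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Named genes were Cftr and Apc, the 10 largest rises and 10 largest falls past the adjusted p with non-overlapping groups, which chance gives for 33.3% of genes at 2 against 2, and a higher group mean of 5 FPKM or more, and up to 4 members with the smallest p of each list discussed. Where fewer passed, the 5 rises and 5 falls with the smallest p are given as not passing. Where colon and duodenum share animals, deviations of the paired specimens correlated across genes at 0.0304 in knockouts and 0.0268 in wildtypes. Of 100 simulated 2-fold changes 74 passed in colon, 60 in duodenum, 80 in ApcMin colon tumours and 76 each in ileum and duodenal tumours. This need not hold for low genes or groups that vary more. Alternatives were a pseudocount of 0.1, no filter, quantile normalisation, the compared groups alone, each run alone, a replicate block, no run term, each specimen left out, and, chosen after seeing the data, the run 1 library of wildtype colon 2 left out, the wildtype duodenum as 2 specimens and, for heterozygous tumours, specimens averaged over runs. Not every list that camera called is described, and those described were chosen after their results were seen. Some genes that the naming rule takes are not reported here.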

Results

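RNA was sequenced from 23 intestinal specimens of C57BL/6 mice aged 3 months to find genes and pathways that differ with Cftr deficiency in Apc wildtype mice and in ApcMin mice. Cftr encodes a chloride and bicarbonate channel of the epithelium. Apc encodes a negative regulator of Wnt signalling, and mice with its Min allele develop intestinal tumours. Normal colon and normal duodenum of Apc wildtype mice were each represented by 2 Cftr wildtype specimens and 2 specimens labelled knockout. Apc wildtype mice labelled knockout also gave 2 duodenal tumours and 1 colon tumour. ApcMin mice gave 2 colon and 2 ileum tumours with wildtype Cftr, 2 colon and 2 ileum tumours labelled knockout, and 2 colon and 2 duodenal tumours from heterozygous animals, which the labels call a knockdown. The 23 specimens carried 10 animal numbers. ApcMin tumours of one Cftr genotype and organ carried 1 animal number, so genotype cannot be told from animal. P-values, also of normal tissue, took their spread partly from such tumours. Xist, the RNA of the inactive X chromosome of females, was at 24.0 to 55.6 FPKM in every ApcMin tumour and at 34.2 FPKM in duodenal tumour 1 of the Apc wildtype mice. In the other specimens it was at 0.0212 to 0.461 FPKM, so the comparisons of ApcMin colon tumours with normal colon were also comparisons of females with males.

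Of the specimens, 11 were sequenced in both of 2 runs and 12 in 1 run, and each library was spread over lanes. From the steps between low values, the relative depth of the 68 columns ranged from 0.731 to 1.34, a 1.84-fold range. The 2 wildtype duodenum specimens differed by less than the sampling noise in run 1, with a between-specimen SD of 0.0771 on the log2 scale against 0.0849 expected from the lanes. In run 2 the SD was 0.106 against 0.0723, a ratio of 1.47, and in the other groups the ratio lay between 2.02 and 8.04. These specimens were counted as 1 sample, which was decided after this check. The run 1 library of wildtype colon 2 differed from the run 2 library of the same specimen by an SD of 0.614, against 0.275 in the colon tumour of the Apc wildtype mouse and 0.115 to 0.175 in 9 other specimens. It held 24 small-intestinal genes at a median of 8.69% of their level in the run 1 library of knockout duodenum 2.

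Principal components of the 14098 tested genes separated the specimens by organ. The second component placed normal tissue at 23.4 to 59.2. The ApcMin Cftr wildtype colon tumours lay far apart on it, at -45.8 for tumour 1 and 3.02 for tumour 2, and the knockout ones at -5.25 and -1.24.

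**Figure D1:**
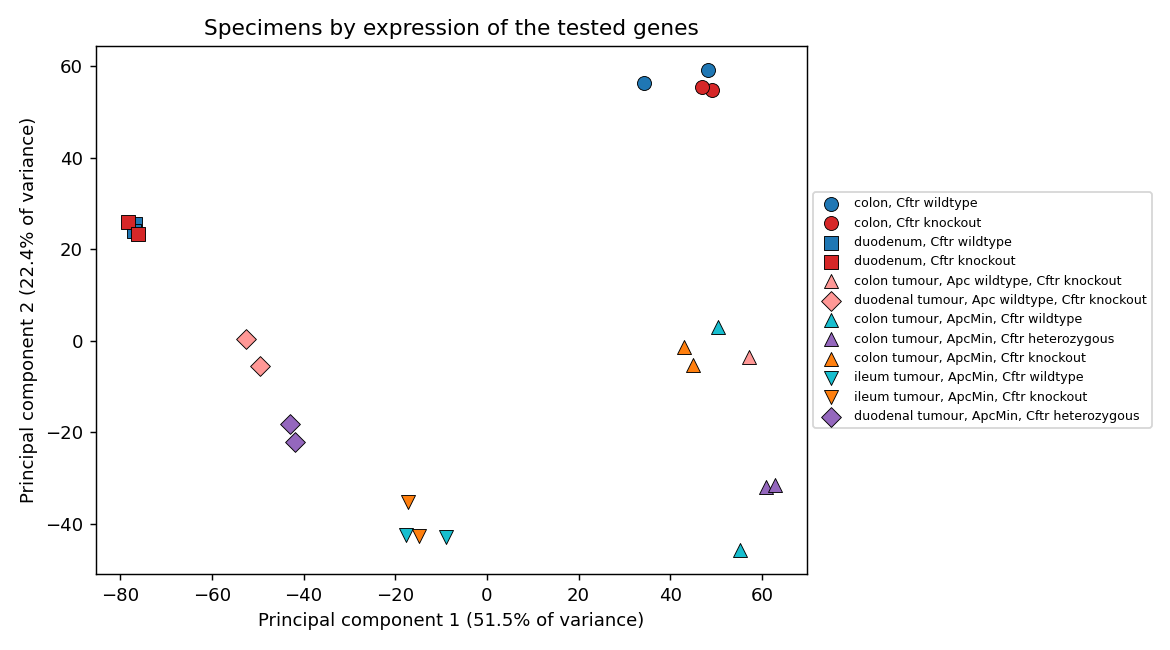
Scores of the 23 specimens on the first principal component (x axis, 51.5% of variance) and the second (y axis, 22.4% of variance) of log2(FPKM + 1), with colour for group. Colon-derived specimens lie at 34.3 to 62.8 on the x axis and small-intestinal specimens at -78.3 to -8.86.

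Cftr RNA (chromosome 6, 18170687 to 18322768, plus strand, build GRCm38) was present in every specimen, including all that were labelled knockout. In colon it was at 30.5 and 25.9 FPKM in the specimens labelled knockout and at 22.2 and 21.7 FPKM in wildtype. In duodenum the values were 33.0 and 47.2 FPKM for labelled knockout and 31.3 and 32.0 FPKM for wildtype. ApcMin colon tumours held 14.3 and 21.3 FPKM when labelled knockout, 12.7 and 9.58 FPKM when heterozygous and 18.0 and 24.8 FPKM when wildtype. Ileum tumours held 40.1 and 31.2 FPKM when labelled knockout and 23.4 and 27.3 FPKM when wildtype. Duodenal tumours held 53.5 and 77.2 FPKM in Apc wildtype mice labelled knockout and 51.7 and 22.1 FPKM in heterozygous ApcMin mice. The colon tumour of an Apc wildtype mouse held 11.2 FPKM. With a floxed allele, a gene-level FPKM sums over deleted and retained exons and other cell types, so the level of Cftr RNA checks no genotype label. Cftr did not pass the test in any comparison. Apc RNA (chromosome 18, 34220924 to 34322552, plus strand) was at 9.85 to 18.2 FPKM in the 23 specimens.

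**Figure D2:**
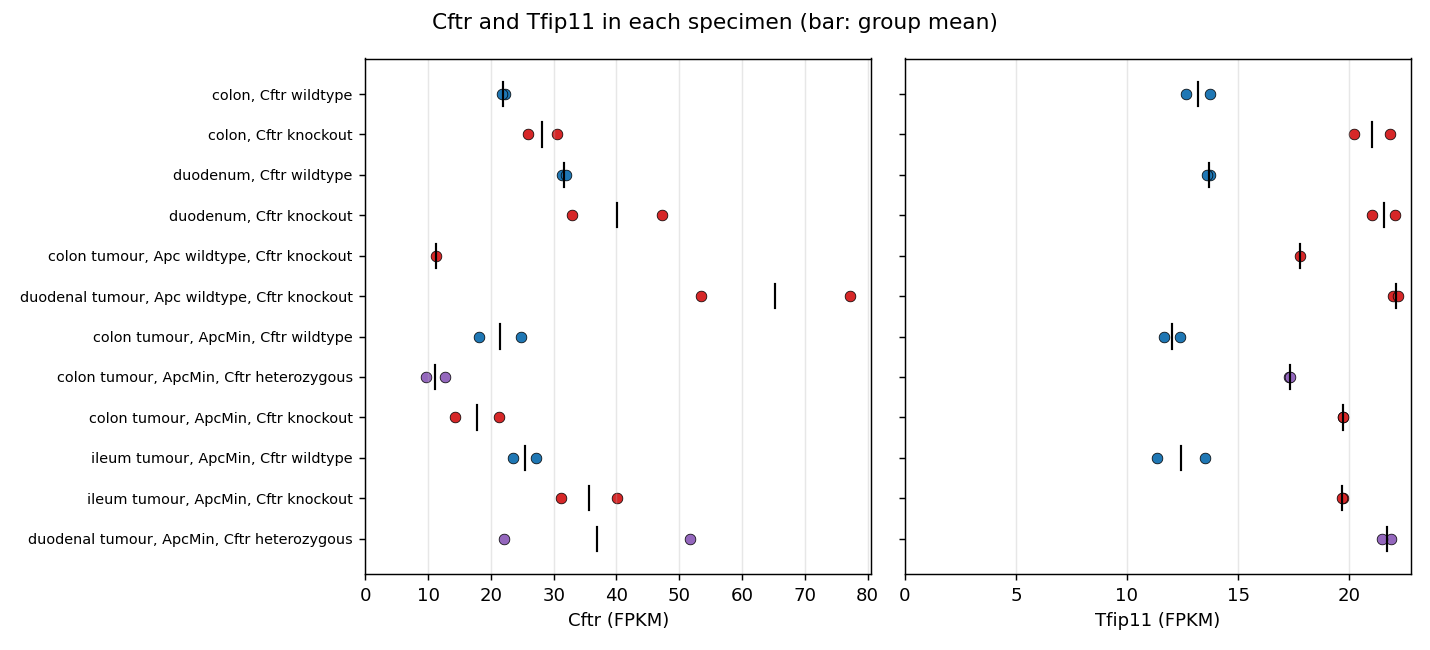
FPKM of Cftr (left) and Tfip11 (right) on the x axes for each specimen in the 12 groups on the y axis, with dots for specimens, bars for group means and colour for Cftr genotype. Cftr overlaps between genotypes, while Tfip11 is higher in all 15 specimens (7 animals) with altered Cftr than in all 8 wildtype ones (3 animals).

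In normal colon, genes of cholesterol synthesis and of proliferation were higher in the specimens labelled knockout as sets, and markers of B cells, T cells and adipocytes were lower (adjusted p = 0.274 for each with an estimated correlation), while no single gene passed the test. All 17 cholesterol synthesis genes had positive changes, with a median log2 change of 0.80. Among them Idi1 was at 95.3 ± 2.08 FPKM (SD, n = 2) against 52.1 ± 14.6 and Fdps at 168 ± 5.02 against 92.9 ± 28.7. Of the 20 proliferation genes 19 were positive, with a median of 0.51 (0.30 without wildtype colon 2). None of the 17 or the 20 passed over all genes tested, and adjusted over the list alone 15 and 13 did. With limma's camera at a preset correlation, the adjusted p was 1.44e-19 for cholesterol synthesis and 4.33e-17 for proliferation.

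Lymphocyte markers were lower as sets. For B and plasma cell markers 3 of 12 changes were positive (median log2 change -1.39, adjusted p = 6.79e-09). For T cell markers the count was 0 of 14 (median -0.52, adjusted p = 1.05e-09; adjusted p = 0.274 for both with an estimated correlation). Adjusted over the list alone, 9 B cell genes passed and no T cell gene did. The B cell co-receptor Cd22 was at 1.29 ± 0.367 FPKM (n = 2) against 6.13 ± 1.00, and Ms4a1, the B cell antigen CD20, at 2.03 ± 0.964 against 11.7 ± 3.39. For MHC class II presentation all 9 changes were negative (median -0.49, adjusted p = 0.00140; adjusted p = 0.560 with an estimated correlation), and the call ended without knockout colon 1 (median -0.19, adjusted p = 0.142), while without knockout colon 2 the median was -0.84. The 9 adipocyte markers (median -1.21, adjusted p = 2.96e-06) and the 10 endothelial markers (median -0.26, adjusted p = 7.63e-05) were all negative too (adjusted p = 0.274 for both with an estimated correlation), and 1 adipocyte gene and no endothelial gene passed over the list alone. The fat droplet protein Plin1 was at 0.963 ± 0.188 FPKM against 3.55 ± 0.749. Higher as sets were the unfolded protein response with 14 of 15 positive (median 0.36, 0.22 without knockout colon 2, adjusted p = 2.96e-06; adjusted p = 0.274 with an estimated correlation). So were immediate early and stress genes with 16 of 17 (median 0.43, adjusted p = 0.000280; adjusted p = 0.397 with an estimated correlation) and epithelial markers with 14 of 14 (median 0.31, adjusted p = 0.000354; adjusted p = 0.525 with an estimated correlation). The epithelial call ended under quantile normalisation (adjusted p = 0.0552), and no member of these 3 lists passed over the list alone. Goblet cell genes were also higher as a set with 13 of 14 positive (median 0.45, adjusted p = 0.00756; adjusted p = 0.535 with an estimated correlation), and enteric neuron and glia markers lower with 0 of 12 (median -0.29, adjusted p = 0.000259; adjusted p = 0.429 with an estimated correlation), with no member of either past the test over the list alone. The goblet call ended without knockout colon 1 (median 0.32, adjusted p = 0.106) and without wildtype colon 2 (median 0.092, adjusted p = 0.462), and the neuron call without knockout colon 2 (median -0.11, adjusted p = 0.138). The goblet median was 0.72 without wildtype colon 1 and the neuron median -0.44 without knockout colon 1.

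Small-intestinal enterocyte genes (3 of 21 positive, median log2 change -0.98, adjusted p = 0.000131; adjusted p = 0.415 with an estimated correlation) and Paneth cell genes (2 of 16, median -1.23, adjusted p = 0.00101; adjusted p = 0.535 with an estimated correlation) were lower as sets in colon labelled knockout. These were the lists that the small-intestinal transcripts in the run 1 library of wildtype colon 2 moved with. The Paneth cell lysozyme Lyz1 was at 10.6 ± 0.807 FPKM (n = 2) against 83.5 ± 89.9, and the small-intestinal chemokine Ccl25 at 2.68 ± 0.362 against 19.7 ± 18.4. Without that library the enterocyte median was -0.11 (adjusted p = 0.871) and the Paneth median 0.033 (adjusted p = 0.871), and without the whole specimen the medians were -0.12 (adjusted p = 0.894) and -0.064 (adjusted p = 0.673). Without wildtype colon 1 they were -1.89 and -2.51. Run 2 alone gave -0.10 (adjusted p = 0.895) and -0.043 (adjusted p = 0.895).

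**Figure D3:**
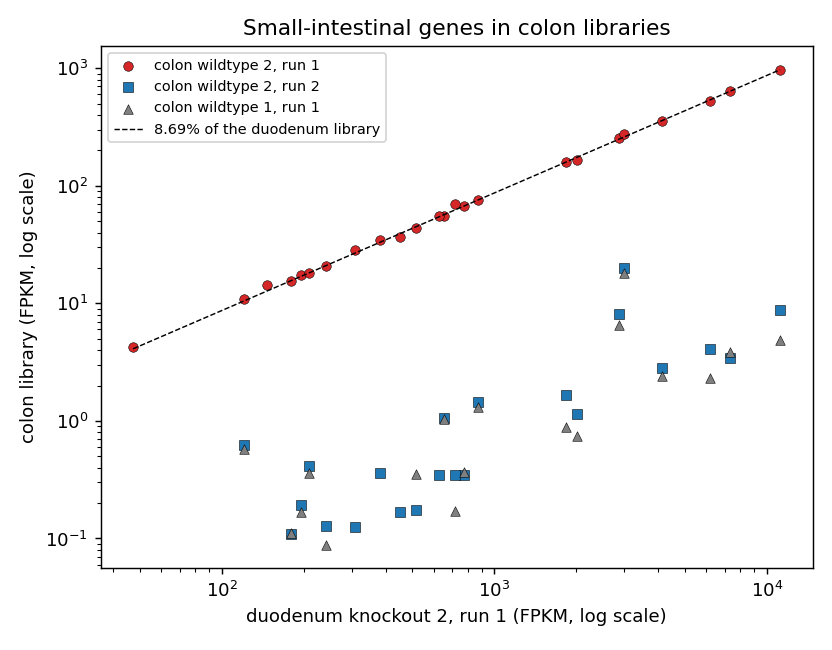
FPKM of 24 small-intestinal genes in 3 colon libraries (y axis, log scale) against the run 1 library of knockout duodenum 2 (x axis, log scale), with values of 0 left out. In run 1 of wildtype colon 2 genes follow the dashed line at 8.69% of the duodenum library, and the other colon libraries lie far below by choice of genes.

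Wnt/beta-catenin targets, intestinal stem cell genes and inflammatory genes are themes that the series description draws from these samples, so counts for them here and in later comparisons are not independent evidence. In colon none of their members passed over all genes or adjusted over the list alone. The Wnt list had 6 of 21 positive changes (median -0.15, adjusted p = 0.511), the stem cell list 5 of 16 (median -0.072, adjusted p = 0.556) and the inflammatory list 15 of 21 (median 0.15, adjusted p = 0.253). Fitted on these groups alone the Wnt list passed (adjusted p = 0.0237), and without knockout colon 1 the inflammatory list did (median 0.35, adjusted p = 0.0434).

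By single genes, 0 of 14098 passed limma's test at an adjusted p of 0.05 in colon, and 931 had an unadjusted p under 0.05. The smallest adjusted p was 0.0880, for Tfip11, a splicing factor gene (chromosome 5, 112326358 to 112338073, plus strand), at 21 ± 1.15 FPKM (n = 2) against 13.2 ± 0.766, a log2 change of 0.64 (SE 0.086). Tfip11 overlaps Srrd on the opposite strand (112337392 to 112343040), so reads in the shared stretch cannot be assigned. Others with the smallest p at the level of the naming rule were, of positive sign, Acta1 (2.28), Ly6g6c (2.03) and Acat2 (0.68). Of negative sign were Ccl25 (-1.60), Mettl7a2 (-1.88) and the lymphocyte GTPases Gimap4 (-1.0), Gimap1 (-0.71) and Gimap3 (-1.11). All these had an adjusted p of 0.379 or above. Cftr (0.34, SE 0.34) and Apc (0.14, SE 0.14) did not pass. Leaving out wildtype colon 1 gave 1 gene and leaving out any other specimen gave 0, and without the filter on low values 16 of 19813 genes passed.

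In normal duodenum, markers of fat, endothelium, macrophages and red cells were lower as sets in the specimens labelled knockout, and genes of cholesterol synthesis were higher (adjusted p = 0.0587 or above with an estimated correlation), again with no single gene past the test. Of 9 adipocyte markers 1 change was positive (median log2 change -2.15, adjusted p = 1.08e-15; adjusted p = 0.0587 with an estimated correlation) and 4 fell when adjusted over the list alone. Plin1 was at 0.672 ± 0.697 FPKM (SD, n = 2) against 5.96 in the merged wildtype sample (n = 1) and the lipase Lpl at 2.74 ± 1.64 against 14.7. Endothelial markers had 0 of 10 positive changes (median -0.41, adjusted p = 6.66e-12; adjusted p = 0.0587 with an estimated correlation). Macrophage and monocyte markers had 1 of 13 (median -0.45, adjusted p = 6.65e-10; adjusted p = 0.0889 with an estimated correlation) and erythroid genes 1 of 5 (median -1.31, -0.79 without wildtype duodenum 2, adjusted p = 0.000333; adjusted p = 0.0587 with an estimated correlation). In these lists 3, 4 and 2 members fell over the list alone. The vessel protein Plvap was at 37.0 ± 0.267 FPKM against 56.6. The macrophage receptor Csf1r was at 14.6 ± 0.397 FPKM against 24.7 and haemoglobin beta Hbb-b1, which has near-identical copies, at 1.86 ± 1.54 against 13.8. All 17 cholesterol synthesis genes were positive (median 0.45, adjusted p = 2.45e-11; adjusted p = 0.318 with an estimated correlation). The median was 0.22 without knockout duodenum 1. None passed over the list alone, and Fdps was at 160 ± 5.12 FPKM against 108. Pancreatic acinar genes were higher as a set with 6 of 7 positive (median 2.70, adjusted p = 0.000333; adjusted p = 0.451 with an estimated correlation) and 0 past the test over the list alone. Ctrl was at 35.3 ± 47.3 FPKM against 1.23 and Prss2 at 88.4 ± 125 against 0.877. That direction came from 1 specimen: without knockout duodenum 1 the acinar median was -0.63 (adjusted p = 0.00470) and without knockout duodenum 2 it was 5.01, and fitted on these groups alone the list did not pass (adjusted p = 0.237).

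None of the members of the study's own themes passed in duodenum, over all genes or adjusted over the list alone, which is not independent evidence. The Wnt list had 5 of 21 positive changes (median log2 change -0.18, adjusted p = 0.441) and the stem cell list 4 of 16 (median -0.23, adjusted p = 0.0912). The inflammatory list had 10 of 21 (adjusted p = 0.657), with a negative median of -0.047, a positive mean of 0.10 and a test pointing up. Fitted on these groups alone the Wnt and stem cell lists passed (adjusted p = 0.00201 each), and without knockout duodenum 2 the stem cell list did (median -0.25, adjusted p = 0.0367) and the inflammatory test pointed down (median -0.11).

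By single genes, 0 of 14098 passed in duodenum by limma and 371 had an unadjusted p under 0.05. Counting the wildtype duodenum as 2 specimens, as designed, gave 33 genes, 7 higher and 26 lower. At the level of the naming rule, genes with the smallest p included Tfip11 at 21.6 ± 0.731 FPKM (n = 2) against 13.7 (n = 1; log2 change 0.62, SE 0.11), Gprin1 (1.05) and the ketone body enzyme Oxct1 (1.04) of positive sign. Of negative sign were Plin1 (-2.13), the desaturase Scd1 (-3.12), the growth hormone receptor Ghr (-1.01) and Lpl (-2.15), and adjusted p values in both directions were 0.124 and above. Cftr (0.31, SE 0.42) and Apc (0.048, SE 0.17) did not pass, and Apc turned to -0.083 without knockout duodenum 2. Run 1 alone gave 0 genes and run 2 alone 1. Leaving out knockout duodenum 1 gave 1 and knockout duodenum 2 gave 18 (13 higher, 5 lower), and without the filter on low values 29 passed.

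The change with Cftr genotype was compared between duodenum and colon as a difference of changes. No gene passed (0 of 14098 by limma, with 314 at an unadjusted p under 0.05). The largest positive differences by p included Oxct1 (1.26, SE 0.31), Nmrk1 (0.63) and Alpk1 (1.17), and the largest negative ones Anxa1 (-1.16, SE 0.29), the monocyte gene Ly6c2 (-1.38), Ednrb (-0.84) and Acta1 (-2.35), all at an adjusted p of 1. Cftr had a difference of -0.034 (SE 0.54), which turned to 0.017 in run 1 alone, 0.22 without knockout duodenum 1 and 0.078 without knockout colon 1. Apc had -0.095 (SE 0.22), which turned to 0.036 without knockout duodenum 1. Run 1 alone gave 0 genes and run 2 alone 1, and leaving out knockout duodenum 2 gave 67 genes (66 higher, 1 lower).

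Between ApcMin colon tumours labelled knockout and wildtype, Tfip11 rose and 8 genes fell. Tfip11 was at 19.7 ± 0.0275 FPKM (SD, n = 2) against 12.0 ± 0.513, a log2 change of 0.67 (SE 0.086, adjusted p = 0.0251). Cxcl14, a chemokine gene (chromosome 13, 56288643 to 56296551), fell from 36.6 ± 9.91 to 11.9 ± 1.90 FPKM. The monocyte gene Ly6c2 fell from 12.7 ± 2.27 to 4.23 ± 0.370 FPKM and the insulin-degrading enzyme Ide (chromosome 19, 37268743 to 37337852) from 27.1 ± 2.59 to 14.9 ± 0.762. Card6 fell from 6.47 ± 0.0205 to 3.18 ± 0.0696 FPKM. Small-intestinal enterocyte genes were higher as a set in the tumours labelled knockout, with 21 of 21 positive (median log2 change 1.66, adjusted p = 7.94e-09; adjusted p = 0.445 with an estimated correlation), and the set kept its call without each specimen in turn. None passed over all genes and 10 adjusted over the list alone. The sucrase Sis was at 11.6 ± 7.53 FPKM against 1.10 ± 0.977 and the peptide transporter Slc15a1 at 43.3 ± 23.6 against 9.21 ± 2.02.

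Wnt targets of these tumours were lower as a set, with 2 of 21 positive (median log2 change -0.72, adjusted p = 1.34e-07; adjusted p = 0.562 with an estimated correlation). None fell over all genes and 5 fell adjusted over the list alone, which is not independent evidence. The Wnt inhibitor Apcdd1 was at 6.11 ± 3.21 FPKM (n = 2) against 33.8 ± 17.8 and the matrix protease Mmp7 at 169 ± 14.2 against 865 ± 715. Neutrophil markers had 0 of 10 positive (median -1.02, adjusted p = 5.37e-06), with 6 that fell over the list alone. Interferon-stimulated genes had 17 of 20 (median 0.39, adjusted p = 0.000300; adjusted p = 0.562 for both with an estimated correlation), with 1 that rose over the list alone. The interferon-induced Oas1a was at 27.9 ± 4.34 FPKM against 13.7 ± 3.16. Colonocyte genes had 15 of 16 positive (median 0.72, adjusted p = 0.0117; adjusted p = 0.562 with an estimated correlation). Goblet cell genes had 10 of 14 (median 0.33, adjusted p = 0.0232; adjusted p = 0.588 with an estimated correlation). No member of these 2 lists passed over the list alone. Hoxd13 was at 51.8 ± 66.7 FPKM against 0.0594 ± 0.00881. The inflammatory list had 8 of 21 positive (median -0.31, adjusted p = 0.0486; adjusted p = 0.726 with an estimated correlation) and 2 that fell over the list alone, not independent evidence. Lcn2 was at 32.2 ± 2.07 FPKM against 154 ± 123. The stem cell list had 3 of 16 positive (median -0.18, adjusted p = 0.173) with none past the test, and Lgr5 was at 6.22 ± 3.50 FPKM against 21.4 ± 18.1.

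The smooth muscle myosin Myh11 was at 5.27 and 73.8 FPKM in wildtype tumours 1 and 2 and at 42.5 and 13.4 FPKM in knockout tumours 1 and 2. Without wildtype tumour 1 the Wnt median was -0.18 (adjusted p = 0.194), the neutrophil median -0.12 (0.122), the colonocyte median -0.44 (0.957), the goblet median -0.12 (0.490) and the stem cell median 0.053. There the inflammatory median turned to 0.58 (adjusted p = 0.0227). Without knockout tumour 2 the inflammatory median was 0.016 (0.480), the goblet median 0.26 (0.101) and the colonocyte median 0.56 (0.0502). Without wildtype tumour 2 the interferon median was 0.31 (0.366) and the stem cell list passed (median -0.48, 0.0141), as it did without knockout tumour 1 (median -0.40, 0.0492). Medians that kept their calls were -1.33 for Wnt, -1.69 for neutrophil, 1.94 for colonocyte, 1.00 for goblet and -1.11 for inflammatory genes without wildtype tumour 2, 0.50 for goblet and -0.51 for inflammatory genes without knockout tumour 1, and -0.61 for neutrophil genes without knockout tumour 2. The inflammatory call also ended with a pseudocount of 0.1 (0.113), without the filter (0.0637), under quantile normalisation (0.102) and in these groups alone (0.407), where goblet cell genes did not pass either (0.0674).

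In all, 1 gene rose and 8 fell of 14098 in these colon tumours, with 1725 at an unadjusted p under 0.05. The count was 1 without knockout tumour 1 or without wildtype tumour 1, 105 without knockout tumour 2 and 1920 without wildtype tumour 2. It was 0 in these groups alone and 27 without the filter, and 0 of the 6 called named genes kept their calls without each specimen in turn. Cftr (-0.26, SE 0.34) and Apc (-0.097, SE 0.14) did not pass, and Cftr turned to 0.013 without knockout tumour 1.

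In ApcMin ileum tumours, Paneth cell and tuft cell genes were higher as sets in the tumours labelled knockout, and macrophage and MHC class II genes were lower (adjusted p = 0.121 or above with an estimated correlation). Defa21 (chromosome 8, 21025545 to 21026516) rose from 0.167 ± 0.0096 to 482 ± 278 FPKM (SD, n = 2; log2 change 8.58, SE 1.26, adjusted p = 0.0210). Defa22 rose from 0.506 ± 0.263 to 587 ± 296 FPKM, Defa20 from 0.321 ± 0.0178 to 454 ± 197, Defa3 from 0.174 ± 0.0103 to 13.6 ± 3.03 and Gm21002 from 1.36 ± 0.263 to 1074 ± 609. These near-identical copies can share reads, and values near 0 belonged to the 1 wildtype animal, whose colon tumours held Defa21 at 0.0698 ± 0.0987 FPKM. Also on chromosome 8, Aga rose from 8.86 ± 1.47 to 16.3 ± 1.29 FPKM and Neil3 from 2.16 ± 0.620 to 5.75 ± 0.402. Both were lowest in that animal, and in normal tissue only Neil3 of colon was higher in knockout. Kcnj16 rose from 0.542 ± 0.0983 to 6.22 ± 0.362 FPKM and Tfip11 from 12.4 ± 1.53 to 19.7 ± 0.0374. Akr1b7, an aldo-keto reductase gene (chromosome 6, 34412334 to 34423142), fell from 46.2 ± 3.93 to 13.2 ± 1.18 FPKM. The protein C receptor Procr (chromosome 2, 155751117 to 155755471) fell from 11.0 ± 0.916 to 5.21 ± 0.118 FPKM and the complement inhibitor Serping1 from 48.9 ± 0.507 to 30.1 ± 4.61.

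Tuft cell genes of the ileum tumours had 11 of 11 positive changes (median log2 change 1.33, adjusted p = 7.21e-12; adjusted p = 0.202 with an estimated correlation), with 0 past the test over all genes and 8 that rose adjusted over the list alone. The taste channel Trpm5 was at 6.43 ± 0.504 FPKM (n = 2) against 1.09 ± 0.00883. Of 16 Paneth cell genes 11 were positive (median 0.74, 0.47 without wildtype tumour 1, adjusted p = 5e-07; adjusted p = 0.486 with an estimated correlation). Of these, 4 rose over all genes and 5 over the list alone. Macrophage and monocyte markers had 1 of 13 positive (median -0.45, adjusted p = 3.77e-11; adjusted p = 0.121 with an estimated correlation). MHC class II presentation had 1 of 9 (median -1.38, adjusted p = 5.12e-06; adjusted p = 0.486 with an estimated correlation). No member of either passed over all genes, and 6 and 4 fell over the list alone. The mannose receptor Mrc1 was at 2.65 ± 0.417 FPKM against 5.83 ± 0.703 and H2-Aa at 72.2 ± 1.41 against 271 ± 40.6. Interferon-stimulated genes had 18 of 20 positive (median 0.37, adjusted p = 2.44e-05; adjusted p = 0.486 with an estimated correlation) with 0 over the list alone and Isg15 at 15.5 ± 2.52 FPKM against 6.03 ± 1.42.

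Members of the study's own themes did not pass in ileum tumours, over all genes or adjusted over the list alone, which is not independent evidence. The Wnt list had 11 of 21 positive changes (adjusted p = 0.844) with a median of 0.038 and a mean of -0.0018. The stem cell list had 11 of 16 (median log2 change 0.12, adjusted p = 0.148) and the inflammatory list 7 of 21 (median -0.24, adjusted p = 0.254). The stem cell (adjusted p = 0.0186) and inflammatory (adjusted p = 0.0241) lists passed when fitted on these groups alone, and the Wnt median turned to -0.21 without knockout tumour 1 and -0.22 without wildtype tumour 2.

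In all, 11 genes rose and 11 fell in ileum tumours, with 829 at an unadjusted p under 0.05. The count was 4 without knockout tumour 1, 2 without knockout tumour 2, 4 without wildtype tumour 1 and 7 without wildtype tumour 2. Of the 14 called named genes 0 kept their calls each time. The count was 13 with a pseudocount of 0.1, 54 without the filter and 120 in these groups alone. Cftr (0.47, SE 0.34) and Apc (-0.056, SE 0.14) did not pass, and Apc turned to 0.094 without knockout tumour 2 and 0.079 without wildtype tumour 1.

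The change with Cftr genotype was then compared between ileum and colon tumours of ApcMin mice. No gene passed (0 of 14098 by limma, 690 at an unadjusted p under 0.05), and the smallest adjusted p was 0.0561, for Akr1b7, with a difference of -2.84 (SE 0.37). Akr1b7 was at 13.2 ± 1.18 FPKM (n = 2) in ileum tumours labelled knockout against 46.2 ± 3.93 and at 3.89 ± 0.313 in colon tumours against 1.36 ± 0.861. The next included Procr (-0.83), the erythroid haem enzyme Alas2 (-1.57) and Cyp3a25 (-2.81) of negative sign, and Defa3 (2.90) and H19 (1.75) of positive sign, all at an adjusted p of 0.679 or above. Cftr (0.73, SE 0.48) and Apc (0.040, SE 0.20) did not pass, and Apc turned to -0.11 without ileum knockout tumour 1 and -0.095 without ileum wildtype tumour 2. Leaving out ileum knockout tumour 1 gave 1 gene and leaving out colon wildtype tumour 2 gave 290 (149 higher, 141 lower), and without the filter 1 passed.

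**Figure D4:**
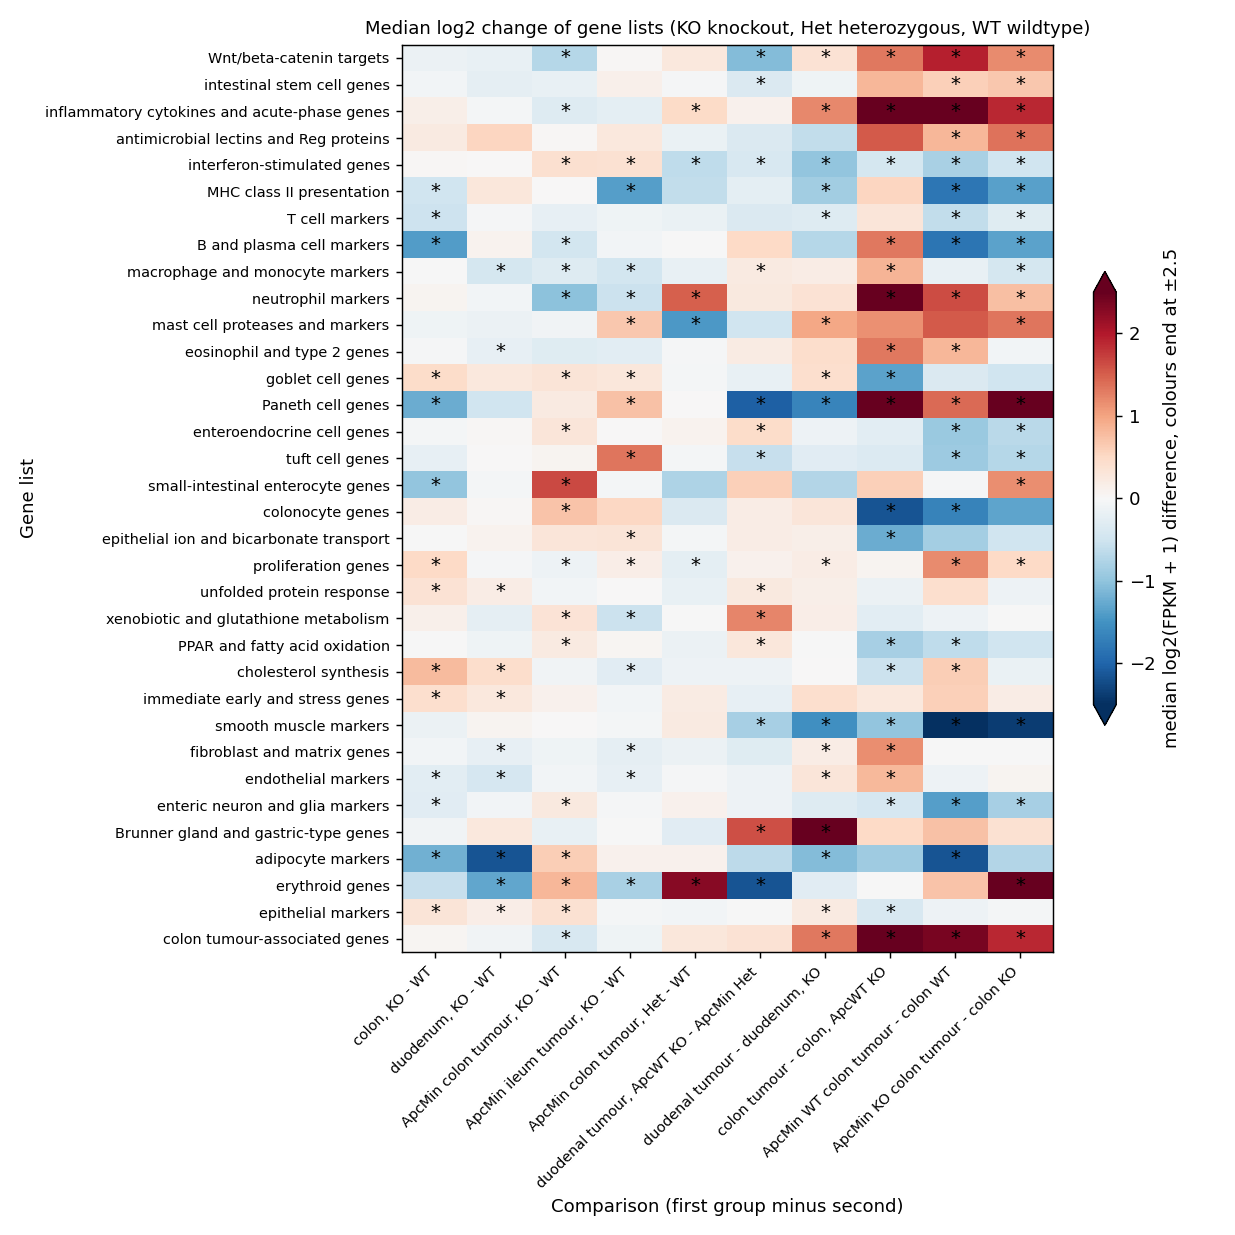
Median log2(FPKM + 1) difference of each gene list (y axis) in 10 comparisons (x axis), with colours ending at 2.5 in either direction and an asterisk where camera at its preset correlation gave an adjusted p under 0.05. The lists drawn passed in at least 2 of the comparisons, and cholesterol synthesis has medians of 0.80 in colon and 0.45 in duodenum.

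Duodenal tumours of Apc wildtype mice labelled knockout were compared with duodenum of other, male mice of that genotype, labelled epithelium. Tumour 1 was female. Brunner gland and gastric-type genes and inflammatory genes were higher as sets, and interferon-stimulated genes were lower (adjusted p = 0.330 or above with an estimated correlation). Anxa10 (chromosome 8, 62057042 to 62123150), an annexin of gastric epithelium, rose from 0.597 ± 0.101 to 299 ± 130 FPKM (SD, n = 2; log2 change 7.49, SE 0.89, adjusted p = 0.000372). The gastric protease cathepsin E, Ctse (chromosome 1, 131638306 to 131675505), rose from 1.87 ± 0.149 to 216 ± 67.0 FPKM and Anxa1 (chromosome 19, 20373428 to 20390944) from 7.44 ± 1.09 to 135 ± 39.9. The stomach peptides Tff1, from 3.64 ± 5.15 to 79.9 ± 53.5 FPKM, and Gkn3, from 7.99 ± 1.95 to 400 ± 511 (log2 change 4.30, 2.16 without tumour 1), rose as well, as did Dpcr1 (4.55) and the mast cell protease Mcpt2 (4.03). Of 11 Brunner gland and gastric-type genes 10 were positive (median 2.82, 1.34 without tumour 1 and 4.67 without tumour 2, adjusted p = 9.64e-06; adjusted p = 0.459 with an estimated correlation). Of these, 3 rose over all genes and 9 adjusted over the list alone. Among the 10 largest falls were the antimicrobial Defa3, from 43.9 ± 3.36 to 5.65 ± 2.13 FPKM, Reg3a (-2.30), the enteroendocrine glucagon gene Gcg, the transporters Slc36a1 (-2.30) and Slc23a1 (-2.68, -1.46 without tumour 2), the detoxifying enzyme Cyp1a1 (-2.66, -1.56 without tumour 1), the pancreatic Ctrl (-3.39, but -1.07 without knockout duodenum 1 and -5.70 without knockout duodenum 2) and Isg15 (-2.11).

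Inflammatory genes of these tumours had 21 of 21 positive changes (median log2 change 1.21, adjusted p = 1.12e-06; adjusted p = 0.459 with an estimated correlation). Of these, 5 rose over all genes and 8 adjusted over the list alone, which is not independent evidence. Saa3 (chromosome 7, 46711998 to 46715700), an acute-phase protein gene, rose from 2.26 ± 1.14 to 26.9 ± 3.72 FPKM (n = 2), S100a9 from 0.744 ± 0.247 to 16.4 ± 5.15 and S100a8 from 0.356 ± 0.0132 to 12.3 ± 1.92. Interferon-stimulated genes had 0 of 20 positive (median -0.99, adjusted p = 7.74e-12; adjusted p = 0.330 with an estimated correlation). Of these, 11 fell over all genes and 18 over the list alone. Isg15 fell from 112 ± 47.9 to 24.0 ± 2.78 FPKM and Ifit3 from 11.5 ± 0.164 to 3.93 ± 0.854. Smooth muscle markers, which belong to the muscle layers, had 0 of 13 positive (median -1.54, adjusted p = 0.000472) with none past the test over all genes or the list alone. Wnt targets had 15 of 21 positive (median 0.35, adjusted p = 0.00924; adjusted p = 0.617 for both with an estimated correlation), with Cd44 alone past the test both over all genes and over the list, not independent evidence. Stem cell genes had 7 of 16 (adjusted p = 0.877), with a negative median of -0.10, a positive mean of 0.081 and a test pointing up. The Wnt call ended without tumour 1 (median -0.077, adjusted p = 0.489) and the smooth muscle call without tumour 2 (median -0.60, adjusted p = 0.122), while the Wnt median was 0.54 without tumour 2 and the smooth muscle median -2.51 without tumour 1. The stem cell test pointed down without tumour 1 (median -0.21) and without knockout duodenum 1 (median -0.18).

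Between these duodenal tumours and duodenum 563 genes rose and 608 fell. The count was 484 without tumour 2, 415 without knockout duodenum 1 and 702 without knockout duodenum 2. It was 215 in these groups alone, and 16 of the 30 called named genes kept their calls each time. Cftr (0.69, SE 0.34) and Apc (0.29, SE 0.14) did not pass.

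The single colon tumour of an Apc wildtype mouse labelled knockout was compared with normal colon of that genotype. In this 1 tumour neutrophil, fibroblast and inflammatory genes were higher as sets and goblet cell genes were lower, by a test that takes its spread from the other groups (adjusted p = 0.321 or above with an estimated correlation). Hp (chromosome 8, 109575128 to 109579172), haptoglobin, rose from 1.67 ± 0.278 (SD, n = 2) to 230 FPKM (n = 1; log2 change 6.46, SE 0.55, adjusted p = 4.83e-05). The matrix proteases rose, Mmp10 from 1.27 ± 0.0860 to 163 FPKM and Mmp7 (chromosome 9, 7692090 to 7699585) from 1.26 ± 0.838 to 224. Spp1 rose from 0.478 ± 0.193 to 152 FPKM and the neutrophil chemokine Cxcl5 from 0.380 ± 0.225 to 76.8. Lyz1 rose from 10.6 ± 0.807 to 748 FPKM. Among the largest falls were the sodium-proton exchanger Slc9a3 from 198 ± 66.6 to 10.7 FPKM and the amino acid transporter subunit Slc3a1 from 33.5 ± 3.62 to 1.93. The glycosyltransferase B4galnt2 fell from 181 ± 5.65 to 9.20 FPKM and the fatty acid binding protein Fabp2 from 734 ± 442 to 41.3. The enteroendocrine hormones Insl5 (-3.99) and Gcg fell, as did Dpep1 (-4.17) and Clca3 (-4.03). The intestinal transcription factor Cdx2 fell from 119 ± 30.4 to 12.3 FPKM.

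Inflammatory genes of the colon tumour had 20 of 21 positive changes (median log2 change 2.98, adjusted p = 1.91e-11; adjusted p = 0.321 with an estimated correlation). Of these, 15 rose over all genes and 16 adjusted over the list alone, not independent evidence. Saa3 rose from 3.79 ± 0.489 (n = 2) to 246 FPKM, S100a8 from 1.61 ± 0.0842 to 223 and S100a9 from 1.64 ± 0.0387 to 206. Neutrophil markers had 10 of 10 positive (median 2.67, adjusted p = 1.47e-07; adjusted p = 0.321 with an estimated correlation). Of these, 7 rose over all genes and 8 over the list alone. Fibroblast and matrix genes had 13 of 15 (median 1.16, adjusted p = 1.1e-07; adjusted p = 0.321 with an estimated correlation). Of these, 9 rose over all genes and 12 over the list alone. Goblet cell genes had 3 of 14 positive (median -1.34, adjusted p = 0.00218; adjusted p = 0.468 with an estimated correlation). Of these, 4 fell over all genes and 7 over the list alone. The mucus proteins fell, Zg16 from 8451 ± 212 to 964 FPKM and Fcgbp from 744 ± 61.8 to 140. Interferon-stimulated genes had 3 of 20 (median -0.45, -0.71 without colon 1, adjusted p = 0.000871; adjusted p = 0.468 with an estimated correlation). Of these, 8 fell over all genes and 9 over the list alone. Rsad2 fell from 3.05 ± 1.17 to 0.564 FPKM. Wnt targets had 21 of 21 positive (median 1.32, adjusted p = 1.1e-07; adjusted p = 0.421 with an estimated correlation). Of these, 9 rose over all genes and 12 over the list alone, not independent evidence. The Wnt inhibitor Wif1 rose from 0.894 ± 0.118 to 24.5 FPKM. Stem cell genes had 13 of 16 positive (median 0.83, adjusted p = 0.0511). Of these, 2 rose and 2 fell over all genes and 8 rose and 2 fell over the list alone, not independent evidence. That list passed under 8 alternatives (adjusted p = 0.0098 to 0.0495), without colon 2 and in run 1 alone among them.

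Against colon, 1014 genes rose and 806 fell in this tumour, which limma assumed to vary like the other groups. Leaving out knockout colon 1 gave 773 and knockout colon 2 gave 719, and 22 of the 33 called named genes kept their calls without each colon specimen in turn. Cftr (-1.25, SE 0.42, adjusted p = 0.0645) and Apc (-0.27, SE 0.17) did not pass.

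Duodenal tumours of Apc wildtype mice labelled knockout were compared with duodenal tumours of a heterozygous ApcMin mouse in run 1, which holds both. Wnt targets and erythroid genes were lower as sets in the Apc wildtype tumours, and xenobiotic and enteroendocrine genes were higher (adjusted p = 0.0850 or above with an estimated correlation). Wif1 (chromosome 10, 121033960 to 121100650) was at 4.09 ± 4.49 FPKM (SD, n = 2) against 44.8 ± 4.49 (log2 change -3.52, SE 0.53, adjusted p = 0.0252), the Wnt feedback gene Axin2 (chromosome 11, 108920349 to 108950783) at 9.47 ± 4.44 against 32.2 ± 1.05 and Lef1 at 0.294 ± 0.355 against 2.65 ± 0.0795. The Wnt list had 2 of 21 positive (median -1.09, adjusted p = 1.79e-09; adjusted p = 0.582 with an estimated correlation). Of these, 3 fell over all genes and 15 adjusted over the list alone, not independent evidence. Erythroid genes had 0 of 5 (median -2.16, adjusted p = 1.02e-05; adjusted p = 0.0850 with an estimated correlation). Of these, 3 fell over all genes and 4 over the list alone. The adult haemoglobins Beta-s (250 ± 4.43 to 17.4 ± 0.665 FPKM), Hbb-b1 (39.9 ± 6.18 to 1.05 ± 1.48) and Hba-a1 (111 ± 38.2 to 2.12 ± 2.97), which share reads with near-identical copies, fell, as did Alas2 (4.40 ± 0.656 to 0.219 ± 0.0194). Other falls included Bpifb5 (-5.16), Bpifb1 (-4.06), the amino acid transporter Slc38a4 (-5.09), albumin, Alb (-4.04) and the cobalamin receptor component Cubn (-3.96).

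Xenobiotic and glutathione genes had 17 of 21 positive changes (median log2 change 1.21, 0.47 without knockout tumour 2 and 0.76 without heterozygous tumour 2, adjusted p = 4.82e-05; adjusted p = 0.732 with an estimated correlation). Of these, 2 rose over all genes and 8 adjusted over the list alone. Gsta3 rose from 10.5 ± 4.38 to 89.7 ± 25.5 FPKM (n = 2). Outside the list rose the oxygenase Fmo1 (chromosome 1, 162829561 to 162866610) from 1.28 ± 0.613 to 10.1 ± 0.111 FPKM. Enteroendocrine genes had 10 of 15 (median 0.46, adjusted p = 0.0275; adjusted p = 0.582 with an estimated correlation). Of these, 3 rose over all genes, and over the list alone 6 rose and 2 fell. Chgb (chromosome 2, 132781278 to 132795079), a secretory granule protein, rose from 34.4 ± 12.2 to 118 ± 9.77 FPKM and the serotonin enzyme Tph1 from 3.96 ± 0.815 to 17.1 ± 0.745. Pdx1, a transcription factor of the duodenum and pancreas, rose from 1.44 ± 1.99 to 42.5 ± 40.3 FPKM, and Slc16a9 (4.05), Insl3 (1.92) and the monocyte gene Ly6c2 (1.15) rose too. Stem cell genes had 2 of 16 positive (median -0.36, adjusted p = 0.00501; adjusted p = 0.732 with an estimated correlation). Of these, 0 fell over all genes and 5 over the list alone, not independent evidence, and Lgr5 was at 2.05 ± 1.61 FPKM against 12.8 ± 6.74. The inflammatory list had 12 of 21 (median 0.10, adjusted p = 0.356). Of these, 0 passed over all genes and 1 fell over the list alone, not independent evidence. The enteroendocrine call ended under quantile normalisation (adjusted p = 0.0578), without knockout tumour 1 (median 0.50, 0.0969) and without heterozygous tumour 1 (median 0.66, 0.252). The stem cell call ended without knockout tumour 2 (median -0.13, 0.0726) and without heterozygous tumour 1 (median -0.20, 0.534), with medians of -0.55 without knockout tumour 1 and -0.59 without heterozygous tumour 2.

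In this comparison of duodenal tumours 64 genes rose and 120 fell, and the difference joins Apc genotype, Cftr genotype, animal and, for tumour 2, sex. The count was 1012 without knockout tumour 1, 25 without knockout tumour 2, 1841 without heterozygous tumour 1 and 98 without heterozygous tumour 2. Of the 26 called named genes 5 kept their calls each time. The count was 0 in these groups alone, 90 with a pseudocount of 0.1 and 54 without the run 1 library of wildtype colon 2. Cftr (0.84, SE 0.37, adjusted p = 0.264) and Apc (-0.052, SE 0.14) did not pass, and Apc turned to 0.14 without knockout tumour 1 and 0.0051 without heterozygous tumour 1.

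ApcMin colon tumours with wildtype Cftr were compared with colon of wildtype mice in run 2. Wnt targets and proliferation genes were higher as sets, and smooth muscle and B cell markers were lower (adjusted p = 0.417 or above with an estimated correlation). The matrix protease Mmp7 rose from 0.739 ± 0.171 to 865 ± 715 FPKM (SD, n = 2; log2 change 8.67, SE 0.52, adjusted p = 6.32e-05) and Mmp10 from 0.567 ± 0.300 to 122 ± 85.3. The antimicrobial lectins rose, Reg3b (chromosome 6, 78370657 to 78373466) from 7.41 ± 1.96 to 1462 ± 1047 FPKM and Reg3g from 5.68 ± 1.93 to 813 ± 102. The phospholipase Pla2g2a rose from 3.79 ± 1.61 to 273 ± 141 FPKM and Lyz1 from 20.9 ± 1.36 to 2457 ± 2537. The pentraxin Mptx1 fell from 7670 ± 4757 to 2.88 ± 0.0782 FPKM and Slc37a2 from 173 ± 7.09 to 1.10 ± 0.416. Clca3 fell from 3437 ± 1810 to 205 ± 197 FPKM and the proton pump Atp12a from 187 ± 43.7 to 5.39 ± 6.65. Insl5 (-4.47) and the fat cell genes Cfd (-5.51) and Car3 (-5.22) fell too. Eif2s3y of the Y chromosome fell from 37.0 ± 1.13 to 0.00968 ± 0.0137 FPKM and Xist (chromosome X, 103460366 to 103483254) rose from 0.0499 ± 0.0328 to 54.7 ± 0.306, the difference of sex.

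Wnt targets had 21 of 21 positive changes in the wildtype tumours (median log2 change 1.94, adjusted p = 4.86e-09; adjusted p = 0.417 with an estimated correlation). Of these, 18 rose over all genes and 19 adjusted over the list alone, not independent evidence. Wif1 rose from 1.10 ± 0.00282 to 103 ± 88.7 FPKM (n = 2) and Apcdd1 from 1.32 ± 0.0503 to 33.8 ± 17.8. Proliferation genes had 20 of 20 (median 1.18, adjusted p = 1.63e-11) and all 20 rose by either adjustment, with Top2a from 15.9 ± 3.91 to 53.9 ± 13 FPKM. Inflammatory genes had 19 of 21 (median 2.55, adjusted p = 7.55e-08; adjusted p = 0.417 for both with an estimated correlation). Of these, 18 rose over all genes, and over the list alone 19 rose and 2 fell, not independent evidence. Saa3 rose from 2.52 ± 1.45 to 112 ± 9.27 FPKM and S100a9 from 0.542 ± 0.545 to 200 ± 206. Stem cell genes had 13 of 16 (median 0.59, adjusted p = 0.0374; adjusted p = 0.505 with an estimated correlation). Of these, 7 rose and 2 fell by either adjustment, not independent evidence. Lgr5 rose from 2.35 ± 0.345 to 21.4 ± 18.1 FPKM. Smooth muscle markers had 0 of 13 (median -2.49, adjusted p = 4.49e-05) and all 13 fell by either adjustment, with Acta2 from 492 ± 13.4 to 105 ± 84.9 FPKM. B and plasma cell markers had 2 of 12 (median -1.83, adjusted p = 0.00110; adjusted p = 0.463 for both with an estimated correlation) with 9 that fell by either adjustment. Interferon-stimulated genes had 3 of 20 (median -0.81, adjusted p = 0.000122; adjusted p = 0.417 with an estimated correlation) with 13 that fell. The stem cell call ended under quantile normalisation (adjusted p = 0.0520), without tumour 1 (median 0.16, 0.213) and without wildtype colon 1 (median 0.61, 0.0653). Its median was 1.07 without tumour 2, and without tumour 1 the Wnt median was 1.17, the smooth muscle median -1.43, the Lgr5 change 1.52 (2.46 with it) and the Acta2 change -1.57 (-2.49 with it).

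In the wildtype ApcMin colon tumours 2687 genes rose and 2659 fell. The count was 2722 without tumour 1, 3414 without wildtype colon 1 and 2360 without wildtype colon 2. It was 356 in these groups alone, and 31 of the 36 called named genes kept their calls each time. Apc rose from 12.9 ± 0.142 to 18.0 ± 0.323 FPKM (n = 2; log2 change 0.45, SE 0.15, adjusted p = 0.0341). That call was lost without each specimen in turn (log2 change 0.43 to 0.46). Cftr (-0.042, SE 0.25) did not pass and turned to 0.18 without tumour 1 and 0.0082 without wildtype colon 1.

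ApcMin colon tumours labelled knockout were compared with colon of Apc wildtype mice labelled knockout in run 2. Wnt targets, inflammatory genes, and genes of Paneth cells and small-intestinal enterocytes were higher as sets (adjusted p = 0.352 or above with an estimated correlation). Mmp7 rose from 1.42 ± 0.686 to 169 ± 14.2 FPKM (SD, n = 2; log2 change 6.16, SE 0.52, adjusted p = 0.000318) and Mmp10 from 1.10 ± 0.146 to 63.0 ± 14.4. Cxcl5 rose from 0.382 ± 0.290 to 45.3 ± 36.0 FPKM, S100a8 from 1.37 ± 0.266 to 68.9 ± 51.2 and Reg3b from 37.8 ± 1.89 to 5244 ± 6414. The lipoprotein gene Apoa1 rose from 4.34 ± 0.0968 to 193 ± 135 FPKM and Apoa4 from 2.56 ± 0.321 to 85.7 ± 67.3. Sis (chromosome 3, 72888557 to 72967863) rose from 0.295 ± 0.0157 to 11.6 ± 7.53 FPKM and the defensin Defa24, which shares reads with copies, from 7.18 ± 1.40 to 455 ± 318. Retnla fell from 13.9 ± 3.67 to 0.451 ± 0.388 FPKM, Slc9a3 from 198 ± 63.1 to 22 ± 18.5 and Mptx1 from 3646 ± 1591 to 184 ± 235 (log2 change -5.40, -3.31 without tumour 2). The neuropeptide galanin, Gal (-2.97), fell too. Ddx3y (-3.74) and Eif2s3y (-4.93) of the Y chromosome fell and Xist (5.61) rose, the difference of sex.

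Paneth cell genes had 14 of 16 positive changes in these tumours (median log2 change 3.42, adjusted p = 4.69e-09; adjusted p = 0.352 with an estimated correlation). Of these, 11 rose over all genes and 14 adjusted over the list alone. Enterocyte genes had 15 of 21 (median 1.16, adjusted p = 2.99e-05; adjusted p = 0.415 with an estimated correlation). Of these, 9 rose over all genes and 11 over the list alone. Wnt targets had 21 of 21 (median 1.19, adjusted p = 6.44e-09; adjusted p = 0.415 with an estimated correlation). Of these, 9 rose over all genes and 13 over the list alone, not independent evidence. Wif1 rose from 0.914 ± 0.172 to 23.7 ± 10.2 FPKM (n = 2). Inflammatory genes had 19 of 21 (median 1.88, adjusted p = 2.36e-09; adjusted p = 0.415 with an estimated correlation). Of these, 13 rose over all genes and 16 over the list alone, not independent evidence. Saa3 rose from 3.77 ± 0.107 to 49.7 ± 16.2 FPKM. Smooth muscle markers had 0 of 13 (median -2.38, adjusted p = 7.73e-07; adjusted p = 0.440 with an estimated correlation). Of these, 3 fell over all genes and 13 over the list alone, with Smtn from 40.7 ± 6.72 to 11.7 ± 2.87 FPKM. Stem cell genes had 13 of 16 (median 0.68, adjusted p = 0.0117; adjusted p = 0.440 with an estimated correlation). Of these, 2 rose and 1 fell over all genes and 5 rose and 1 fell over the list alone, not independent evidence, with Ly6a from 312 ± 179 to 725 ± 1.11 FPKM (log2 change 1.34, 0.72 without knockout colon 1). The stem cell call ended without tumour 1 (median 0.51, adjusted p = 0.0755).

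In the ApcMin colon tumours labelled knockout 743 genes rose and 793 fell. The count was 759 without tumour 1, 500 without tumour 2, 218 without knockout colon 1 and 499 without knockout colon 2. It was 718 in these groups alone, and 12 of the 32 called named genes kept their calls each time. Cftr (-0.71, SE 0.25, adjusted p = 0.0852) and Apc (0.20, SE 0.15) did not pass.

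Heterozygous ApcMin colon tumours, sequenced in run 1, were compared with wildtype ApcMin colon tumours, sequenced in run 2, with a run term estimated from the 11 specimens in both runs. Neutrophil markers were higher as a set, and mast cell and interferon-stimulated genes were lower, though not by fry (adjusted p = 0.255 and 0.0749) or without wildtype tumour 1 (adjusted p = 0.703 and 0.0839). Ngp (chromosome 9, 110419747 to 110423012), a neutrophil granule protein, rose from 1.04 ± 1.13 to 26.8 ± 4.75 FPKM (SD, n = 2; log2 change 3.88, SE 0.22, adjusted p = 3.53e-10) and Stfa2 from 1.46 ± 0.849 to 15.2 ± 1.47. The small proline-rich protein gene Sprr2b rose from 5.23 ± 6.76 to 74.0 ± 31.7 FPKM. The caspase Casp14 rose from 0.608 ± 0.835 to 11.1 ± 2.92 FPKM and Mptx1 from 2.88 ± 0.0782 to 90.9 ± 53.9. Ido1 (chromosome 8, 24584136 to 24597009), a tryptophan-degrading enzyme, fell from 6.35 ± 0.513 to 0.241 ± 0.0400 FPKM. The mucosal mast cell protease Mcpt1 fell from 27.4 ± 11.4 to 2.73 ± 1.53 FPKM and the mucin Muc4 from 15.1 ± 7.67 to 3.12 ± 0.832. The carbonic anhydrase Car12 fell from 19.1 ± 17 to 1.96 ± 0.708 FPKM, Apol10a from 44.0 ± 50.2 to 1.07 ± 0.822 and B4galnt2 from 107 ± 69.2 to 22.8 ± 11.8. Clca6 (-2.39) and Dhrs9 (-1.45) fell as well. Without wildtype tumour 2 the log2 changes were 2.64 for Sprr2b (4.10 with it), -1.45 for Car12 (-2.44), -2.35 for Apol10a (-3.89), -1.34 for B4galnt2 (-2.04) and -1.43 for Clca6.

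Neutrophil markers had 9 of 10 positive changes in the heterozygous tumours (median log2 change 1.5, adjusted p = 1.9e-15; fry adjusted p = 0.000130). Of these, 3 rose over all genes and 8 adjusted over the list alone, with Mmp8 from 2.42 ± 2.09 to 7.80 ± 1.01 FPKM (n = 2). An estimated correlation could not be had in this fit, so fry, which asks whether a list's genes move one way on balance, is given beside camera. Interferon-stimulated genes had 2 of 20 (median -0.63, adjusted p = 1.75e-06; fry adjusted p = 0.0749). Of these, 1 fell over all genes and 12 over the list alone. Mast cell genes had 3 of 10 (median -1.43, adjusted p = 0.00166; fry adjusted p = 0.255). Of these, 1 fell over all genes and 6 over the list alone. Proliferation genes had 0 of 20 (median -0.25, adjusted p = 0.000577; fry adjusted p = 0.477). Of these, 1 fell over all genes and 3 over the list alone, with Mki67 from 25.7 ± 1.07 to 13.6 ± 0.704 FPKM. Erythroid genes had 5 of 5 (median 2.28, adjusted p = 0.0392; fry adjusted p = 9.18e-05). Of these, 1 rose by either adjustment, Alas2, from 2.64 ± 1.2 to 9.56 ± 0.654 FPKM. Inflammatory genes had 17 of 21 (median 0.47, adjusted p = 0.0350; fry adjusted p = 0.535). Of these, 0 were past the test over all genes and 1 over the list alone, not independent evidence. The Wnt list had 16 of 21 (median 0.26, adjusted p = 0.253) with none past the test and Axin2 at 67.3 ± 4.66 FPKM against 45.9 ± 32.5. The stem cell list had 8 of 16 (adjusted p = 0.979), with a negative median of -0.027, a positive mean of 0.034 and 1 that rose by either adjustment, Hopx, from 46.3 ± 23.4 to 104 ± 1.04 FPKM, not independent evidence.

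Without wildtype tumour 1 the interferon (median -0.43, adjusted p = 0.0839), mast cell (median -0.69, 0.703), proliferation (median -0.10, 0.401) and erythroid (median 2.97, 0.0794) calls ended, the Wnt list passed at a median of 1.07 and the inflammatory median was 1.33. Without wildtype tumour 2 the Wnt median turned to -0.30 (0.0149), the inflammatory median to -0.28, the neutrophil median was 0.97 and the erythroid call ended (median 1.93, 0.111). Without heterozygous tumour 2 the erythroid (median 2.64, 0.0683) and inflammatory (median 0.42, 0.0683) calls ended, as they did with a pseudocount of 0.1 (0.214 and 0.125). The stem cell test pointed down without heterozygous tumour 1 (median -0.13) and without wildtype tumour 2 (median -0.32), and without wildtype tumour 2 Axin2 turned to -0.10, Mmp8 was at 0.84 (1.51 with it) and Hopx at 0.57 (1.10).

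In heterozygous against wildtype colon tumours 135 genes rose and 121 fell. Both runs of 11 specimens entered that fit, which so had 19 residual degrees of freedom against 10 for specimens. With specimens averaged over runs and no run term, chosen after seeing the data, 456 genes passed, 182 of them among the 256, Ngp and Stfa2 included. The calls of Mcpt1, Car12, Apol10a, B4galnt2, Clca6, Dhrs9 and Mptx1 ended there, as did that of the inflammatory list (adjusted p = 0.0672). Quantile normalisation gave 226 higher and 277 lower, and 504 genes passed without the run term and 482 without the filter. The count was 42 without heterozygous tumour 1, 15 without heterozygous tumour 2 and 1933 without wildtype tumour 1, and 2 of the 26 called named genes, Ngp and Stfa2, kept their calls each time. Cftr (-0.81, SE 0.28, adjusted p = 0.131) and Apc (-0.38, SE 0.12, adjusted p = 0.0910) did not pass.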

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

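The patterns weighed in the last part rest on tests chosen after the results were seen, while the differences of changes given here were planned. Each list here passed camera at its preset correlation for a difference of the Cftr-genotype change between organs.

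For duodenum minus colon, 5 of 12 lists kept their calls without each specimen in turn, with median differences (and their range then) of 1.60 (0.50 to 2.70) for B and plasma cell markers, 0.53 (0.34 to 0.59) for T cell markers, -0.50 for macrophage and monocyte markers, -0.57 (-0.74 to -0.38) for proliferation and -0.21 for neighbours of Cftr on the chromosome. The others were 0.85 (-0.12 to 1.82) for MHC class II presentation, 3.01 (-0.47 to 5.39) for pancreatic acinar genes, -0.92 (-1.40 to -0.39) for adipocyte markers, 0.87 (0.19 to 1.65) for small-intestinal enterocyte genes, 0.21 (0.15 to 0.37) for enteric neuron and glia markers, -0.30 (-0.54 to -0.046) for cholesterol synthesis and -0.10 (-0.23 to -0.017) for endothelial markers. The first 3 of these calls ended without knockout duodenum 1, where the acinar difference turned, the enterocyte call without wildtype colon 2, whose run 1 library held small-intestinal transcripts, and the last 3 each when any 1 of 3 specimens was left out. The smallest adjusted p with an estimated correlation was 0.224.

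For ileum minus colon tumours of ApcMin mice, 4 of 15 lists kept their calls each time, at 0.95 for tuft cell genes, -1.40 for MHC class II presentation, -1.77 for enterocyte genes and -1.92 (-3.01 without knockout colon tumour 1) for erythroid genes, the 1 list of 27 that passed with an estimated correlation (adjusted p = 0.0343). Without wildtype colon tumour 1 the calls ended for Wnt targets at 0.79 (0.27 to 1.66), stem cell genes at 0.47 (0.17 to 0.83), neutrophil markers at 0.54 (-0.16 to 1.22), mast cell genes at 0.51 (-0.015 to 1.24), Paneth cell genes at 1.42 (0.64 to 2.81), xenobiotic and glutathione genes at -0.72 (-0.84 to -0.18), PPAR and fatty acid oxidation at -0.26 (-0.70 to 0.11), enteric neuron and glia markers at -0.25 (-0.52 to -0.077), adipocyte markers at -1.11 (-1.49 to -0.28) and epithelial markers at -0.43 (-0.86 to -0.17). The proliferation call at 0.30 (0.19 to 0.46) ended without knockout colon tumour 1.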

How the results depend on the processing

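The library left out, the wildtype duodenum as 2 specimens and specimens averaged over runs were chosen after seeing the data, and all others were planned. Under settings other than leaving out a specimen, 2006 values of single genes kept direction and call, 194 lost the call, 41 gained it and 1 turned, and of lists 758, 36, 12 and 6. With a specimen left out these were 1018, 280, 29 and 15 for genes and 457, 71, 6 and 16 for lists. FPKM carries no counts, so depth limits low genes by an unknown amount. The cause was not tested for any change given here, except that leaving out specimens or groups leaves fewer samples and no filter tests more genes. A lone remaining specimen was assumed to vary like the other groups.

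Without the filter 16 genes passed in colon, 29 in duodenum, 27 in ApcMin colon tumours, 54 in ileum tumours, 5 for duodenum against colon, 1 for ileum against colon tumours and 482 for heterozygous against wildtype. A pseudocount of 0.1 gave 13 in ileum tumours and 90 between duodenal tumours. Groups alone gave 0 in ApcMin colon tumours, 120 in ileum tumours, 215 for duodenal tumour against duodenum, 0 between duodenal tumours, and 356 and 718 for wildtype and knockout ApcMin tumours against colon. Run 2 alone gave 1 in duodenum and 1 for duodenum against colon. Heterozygous against wildtype gave 503 under quantile normalisation, 504 without the run term and 456 with specimens averaged over runs. The wildtype duodenum as 2 specimens gave 33, and leaving out the run 1 library of wildtype colon 2 gave 54 between duodenal tumours. Of 183 list calls, 54 passed with fry, which called 62, and 1 with an estimated correlation, which could not be had for 6 of them. Between knockout and wildtype, fry called 0 lists in colon, duodenum, ApcMin colon tumours and ileum tumours (8, 4, 5 and 5 at an unadjusted p under 0.05), where camera called 14, 11, 18 and 15.

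With replicate numbers as a block the counts were 8 in duodenum, 50 in ApcMin colon tumours, 719 for the colon tumour against colon and 420 between duodenal tumours. Those specimens share only a number, and where colon and duodenum are paired by animal the block changed no call.

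Leaving out each specimen gave 0 to 1 genes in colon, 0 to 18 in duodenum, 1 to 1920 in ApcMin colon tumours, 2 to 7 in ileum tumours, 0 to 67 for duodenum against colon, 0 to 290 for ileum against colon tumours, 415 to 1043 for duodenal tumour against duodenum, 719 to 773 for the colon tumour, 25 to 1841 between duodenal tumours, 2360 to 6622 and 218 to 759 for wildtype and knockout ApcMin tumours against colon, and 15 to 1933 for heterozygous against wildtype.

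The test turned down to the side of an already negative median in groups alone for inflammatory genes in duodenum (-0.047) and stem cell genes in duodenal tumours (-0.10, in run 1 -0.10), and for stem cell genes in heterozygous tumours without the filter (-0.027) and without the run term, averaged or not (-0.031). Cftr for duodenum against colon turned to 0.017 in run 1. Over left-out specimens, duodenum ran from -0.083 to 0.18 for Apc, -0.49 to 6.68 for Prss2, duodenum, Cftr knockout against wildtype, -0.63 to 5.01 for acinar genes and -0.11 to 0.0085 for inflammatory genes. ApcMin colon tumours ran from -0.54 to 0.013 for Cftr, -0.12 to 1.00 for goblet cell genes, -0.48 to 0.053 for stem cell genes and -1.11 to 0.58 for inflammatory genes. Ileum tumours ran from -0.21 to 0.094 for Apc and -0.22 to 0.27 for Wnt targets. Duodenum against colon ran from -0.23 to 0.036 for Apc, -0.29 to 0.22 for Cftr and -0.47 to 5.39 for acinar genes, and ileum against colon tumours from -0.11 to 0.19 for Apc, -0.16 to 1.22 for neutrophil markers and -0.70 to 0.11 for PPAR and fatty acid oxidation. Stem cell genes of duodenal tumours ran from -0.21 to 0.28, Apc between duodenal tumours from -0.24 to 0.14 and Cftr of wildtype ApcMin tumours against colon from -0.26 to 0.18. Heterozygous tumours ran from -0.10 to 1.44 for Axin2, -0.30 to 1.07 for Wnt targets, -0.32 to 0.29 for stem cell genes and -0.28 to 1.33 for inflammatory genes.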

Other observations

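All tests in this part were chosen after the results they bear on were seen, and the test on Hoxd13 replaced an earlier one between genotypes.

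The run 1 library of wildtype colon 2 held 24 small-intestinal genes at 8.58% to 8.99% (quartiles) of their level in the run 1 library of knockout duodenum 2. In run 2 their median was 0.00739 of run 1. Genes were chosen as over 100 times below duodenum there, so the specimen's own RNA was not tested. Carry-over from that duodenum library may account for the pattern, as it would give 1 ratio for every gene, and the upper quartile was 1.05 times the lower.

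ApcMin colon tumours labelled knockout held 24 ileum-type transcripts at medians of 8.29% and 3.11% of ileum tumours labelled knockout, against 0.690% in wildtype colon tumours. Without 4 defensins under 1 FPKM in the wildtype ileum tumours these were 8.45%, 3.38% and 1.14%, and wildtype colon tumours were at 2.33% of wildtype ileum tumours, while 7 of the 24, Lyz1 and Mmp7 among them, were lower than in wildtype colon tumours. Carry-over from ileum tumour libraries could give this, but the upper quartiles of these ratios were 1.61 and 1.80 times the lower, between the bounds set for and against it. Place along the colon, read from Hoxd13, stays open too. In the heterozygous tumour with more Hoxd13, 21 of these genes had a median of 1.34 times the other (quartiles 0.719 to 2.93). Cftr genotype cannot be told apart from animal here.

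Tfip11 was at 17.3 to 22.2 FPKM in 15 specimens (7 animals) with altered Cftr and 11.4 to 13.8 in 8 wildtype ones (3 animals). Its overlapping neighbour Srrd was at 12.8 to 17.3 against 7.18 to 11.2 FPKM. An extra copy that also holds the neighbour Tpst2 is argued against by Tpst2 folds of 1.04 and 1.02 in knockout colon and ileum tumours. The other 3 comparisons gave 1.26 to 1.41. One of Tfip11 and Srrd stays open. Tfip11 folds over wildtype ran from 1.44 in heterozygous to 1.64 in knockout colon tumours, against 1.5 for 3 copies. The heterozygous Srrd fold was 2.11, past its set bound by under 2 standard errors. These heterozygous folds crossed runs with no run term. A shared chromosome 5 stretch from another strain stays open. Of 176 genes within 10 Mb, 5 shifted one way in all 4 knockout comparisons, whose organs share animals, against 185 of 13038 elsewhere (Fisher's exact test, p = 0.110). A response to Cftr dose stays open, with heterozygous over knockout tumours at 0.930 for Tfip11 and 1.17 for Srrd. Each averages a colon ratio across runs and a duodenal one across Apc genotypes. A biological Cftr effect was not separable from the other explanations.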
